A study of Schizosaccharomyces pombe with 26 samples.

How the data were processed

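The series holds 26 samples: Med15-myc ChIP and histone H3 ChIP on spotted 2-colour arrays of intergenic regions (IGR) and open reading frames (ORF), and RNA on Affymetrix arrays. The comparisons, tests, alternatives, the rule for named genes and 29 gene lists were written from the labels before the data were examined, and so were 2 of the tests of explanations in the closing section (regions that give a high ratio with any antibody, and the side of the gene on which an IGR feature lies). All other additions are named as such below.

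For the spotted arrays, per the file headers the scanner tables hold the median intensity of the spot and of its local background for each of 9902 IGR and 9736 ORF spots and each dye, with no correction by the authors. The dye of the ChIP DNA was taken from the labels. The deposited value table of these arrays holds log2 values; comparison with the scanner tables shows for the deletion and Med15-myc samples that the authors took the ChIP channel less its background over a constant, with a floor, and did not divide by input. Correlation with the background-subtracted ChIP channel was 0.991 or more. The wildtype H3 columns have the same form, but no scanner tables of these samples were at hand, so their make-up is inferred. For the Affymetrix arrays, the deposited intensity values are signals of each probe set on a linear scale that the authors scaled so that every array has the same trimmed mean, as the values show, with software the labels do not state, and log2 was taken here.

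For Med15-myc, the log2 ratio of the ChIP over the input intensity was taken as scanned, without background correction and without loess, spots of a feature averaged, control spots left out, and each array centred on its median. limma 3.58.1 in R 4.3.3 (lmFit, eBayes) tested the mean of 3 samples against 0. For H3, the plan was to use ratios, but the value table holds the ChIP channel alone and wildtype has no input, so the deposited log2 values were centred on each array's median, values at the floor were treated as missing, and all 7 samples of an array type entered a limma fit with strain and dye of the ChIP DNA. All wildtype H3 samples have the ChIP DNA in Cy3, so the dye term is estimated from the deletion samples alone and carried over to the comparisons with wildtype. The fitted values are differences in H3 ChIP signal and not in occupancy. For RNA, the 6 samples entered a limma fit by strain on the 8572 of 10928 probe sets whose mean log2 signal over all arrays was above −1.20, a quantile fixed in the plan, 213 control probe sets left out. The plan was to test *S. pombe* probe sets only, with this quantile for the case that species could not be told. Species could not be told here, so the tested probe sets may include ones for *S. cerevisiae*. All p-values were two-sided from the moderated t-test of limma on 2 or 3 samples per strain, adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Errors after ± are standard errors of the fit.

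Gene names come from the files, joined to the given gene table of assembly ASM294v3: of IGR features 4579 matched 1 gene, 16 several and 354 none, and of ORF features 4649, 13 and 195. The genome build of the array design is not given in the sources used here, so no coordinates are printed. An IGR feature carries the name of a gene, and on which side of that gene it lies is not stated in the files. No table that names the genes of Affymetrix probe sets was at hand, so RNA results are given by probe set except for named controls, and the gene list tests on RNA and every relation between RNA and ChIP that had been planned were not run.

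Named features follow a rule fixed beforehand: *med15* and *hrp1* first, then the 10 largest rises and the 10 largest falls that pass and whose samples of each group do not overlap (for Med15-myc the 10 highest), or, where fewer than 10 pass, the 5 largest each way with unadjusted p < 0.05, said not to pass, then 4 members of each list that passes or has 3 or more called members. Of the features this rule names, 2 are not reported here. For probe sets without names at most 2 each way are printed, without a size where 1 of the strains read near background. Members of copied gene families are marked uncertain because spotted DNA of copies cross-hybridises. The features named from the normexp values and the control probe sets were chosen after the values were seen.

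Lists were tested with camera at the preset correlation of 0.01, with camera at a correlation estimated from the data and with fry as alternatives (camera asks whether a list differs from the other features, fry whether it differs from no change), over lists with 5 or more measured members. For H3 these tests and the counts of called members use features measured in every sample. Sharing between deletions was compared with independence and with 100 simulated pairs of unchanged groups that share the wildtype arrays. Relations between H3 change and Med15-myc ratio used Spearman and Pearson coefficients with 100000 permutations. A self-test added known shifts to 100 features: a log2 shift of 2 was recovered at 0% (IGR) and 27% (ORF) of features for Med15-myc as scanned, 98% and 100% with normexp, 11% (IGR) and 60% (ORF) for H3 in Δhrp1, 4% and 23% in Δmed15, and 63% for RNA in Δmed15 and 64% in Δhrp1. Among 28 lists, camera called the shifted one (adjusted p = 8.50e-138) and 0 of the others. The simulated features were independent, so this does not test the preset correlation.

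Alternatives fixed before the data were examined covered background correction with normexp (offset 50), loess (span 0.3), the deposited values for Med15-myc, dim features, dye, scaling, missing values, a replicate block, a threshold of 1.5-fold, an offset of 16, a mean-variance trend and leaving out each sample. Added after the data were seen were local background subtraction, normexp with loess, floor values kept for H3, ChIP over input with normexp or loess for the 5 deletion samples of H3, list tests on normexp and loess values (for H3 on ChIP over input), leave-one-out fits on them for Med15-myc, the stricter filter for shared and leave-one-out RNA calls, Med15-myc values with normexp or loess in the relations, and a wildtype array of its own for each deletion in the sharing. For Med15-myc, 5 treatments of the scanner values were compared, and the one fixed beforehand stays the reported one although it calls nothing. The tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.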

Results

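The 26 samples came from 4 strains of *Schizosaccharomyces pombe* harvested in logarithmic growth on a rich medium. Med15 is a tail subunit of Mediator, the complex that links transcription factors to RNA polymerase II, and Hrp1 is a chromatin remodelling ATPase of the CHD1 type. Chromatin immunoprecipitation (ChIP) of myc-tagged Med15 was measured in 3 samples on spotted arrays of intergenic regions (IGR) and in 3 on arrays of open reading frames (ORF). Histone H3 ChIP was measured on each array type in 2 wildtype samples, 2 of a strain lacking *med15* (Δmed15) and 3 of a strain lacking *hrp1* (Δhrp1). RNA of wildtype, Δmed15 and Δhrp1 was measured in 2 samples each. The median ChIP signal of an array was 2582 to 12176 scanner units for Med15-myc and 612 to 9458 for H3, over local backgrounds of up to 4989. Duplicate spots in the ChIP channel correlated with r of 0.849 to 0.984. The labels call the replicates biological without saying that each came from its own culture, so p-values measure only the spread between these samples, and the small number of arrays limits the precision. No untagged control is in the labels.

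The deleted genes could be read from the H3 ChIP signal of their own ORF features, which needs their DNA to be present. At *hrp1* the log2 signal was 1.51 and 1.44 in wildtype and 1.91 and 1.46 in Δmed15, against −5.90, −5.93 and −5.56 in Δhrp1 (limma, adjusted p = 0.000246 against wildtype). At *med15* it was −1.76 and −1.41 in wildtype and −4.70 and −3.97 in Δmed15 (adjusted p = 0.029). In the strain that lacks the gene these signals were near background (ChIP channel over local background, 59 over 5, 164 over 9 and 1745.75 over 1624.5 scanner units at *hrp1*; at *med15* about the level of the LacZ control spots), so only a lower bound on the size of each fall can be read. The same level was applied, after the data were seen, to the H3 differences below. Where the mean of 1 strain was −3.97 or lower, the highest reading of a deleted gene in its own strain, they are marked as near background. Their sizes come from the fit with dye and can exceed the difference between strain means. The marked sizes are therefore not exact and are not lower bounds. In Δhrp1 the *med15* feature read −0.51, 0.29 and −0.21, a change of 1.52 ± 0.42 (adjusted p = 0.032). Between the deletions, *med15* was higher and *hrp1* lower in Δhrp1 (adjusted p = 0.00639 and 0.00045). On the IGR arrays, the intergenic features of *med15* differed from wildtype by −2.42 ± 1.20 in Δmed15 and −2.68 ± 1.05 in Δhrp1, and those of *hrp1* by 0.27 and −1.51 ± 0.61, none past the threshold (adjusted p = 0.113 to 0.86). In the Med15-myc strain, the *med15* ORF ratio of ChIP over input was −0.03 ± 0.30 and its IGR ratio 1.32 ± 0.92, and those of *hrp1* were 0.15 ± 0.34 and 0.16 ± 0.47, with none called by limma.

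**Figure D1:**
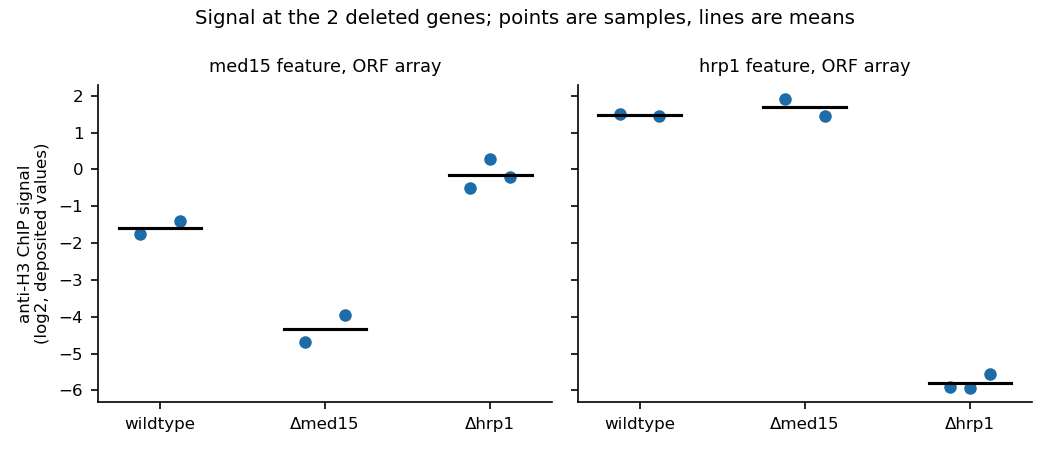
Log2 anti-H3 ChIP signal at the *med15* and *hrp1* ORF features in each sample, with a line at each strain's mean. Both genes read low in the strain that lacks them.

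Med15-myc ratios over IGR features were highest at the features named after SPAP15E9.02c (log2 3.02 ± 0.60), SPAC17A2.10c (2.63 ± 0.47), SPAC27E2.11c (2.44 ± 0.45), the glycerol-3-phosphate dehydrogenase gene *gpd1* (2.32 ± 0.51) and the proteasome gene *rpn502* (2.23 ± 0.43). They were lowest at *pab2*, which encodes a nuclear poly(A)-binding protein (−1.71 ± 0.59), the chromatin assembly factor gene *pcf2* (−1.66 ± 0.65), *mto2* (−1.42 ± 0.47), *utp16* (−1.40 ± 0.51) and the RNA polymerase III gene *rpc34* (−1.38 ± 0.52). None of these passes the test: limma called 0 of 4949 IGR features on the ratios as scanned (adjusted p = 0.9999 for each named feature), with 30 higher and 6 lower at unadjusted p < 0.05. Background correction with normexp called 61 features higher and 55 lower, with 20 higher and 6 lower without replicate 1, 90 and 102 without replicate 2, and 37 and 0 without replicate 3. Loess called 165 higher and 339 lower (25 and 68, 83 and 228, and 257 and 260 in turn), and 48 were called higher by both. Under normexp, the highest features lay at SPAC17A2.10c (3.01 ± 0.35, adjusted p = 4.24e-09), SPAP15E9.02c (2.92 ± 0.36), SPAC27E2.11c (2.83), *gpd1* (2.72), the H2A gene *hta1* (2.65), *prt2*, a long noncoding RNA gene next to *pho84* (2.63), the malic enzyme gene *mae2* (2.60), the pyruvate decarboxylase gene *pdc101* (2.45), SPAC17A2.11 (2.37) and a long intergenic tile at SPAP15E9.02c (2.35). The *med15* IGR feature was also called in that setting (1.52 ± 0.36, adjusted p = 0.00683), and *hrp1* was at −0.18 (adjusted p = 0.852). Input at this *med15* feature was dim, at 3190 over a local background of 2243, 196 over 0 and 7764 over 7910 in replicates 1 to 3. The ChIP channel there lay below the array median in each replicate, so the call rests on a ratio over dim input. As scanned, the replicate with the opposite dye ran against the others (Spearman rho of −0.19 and −0.39), so the calls rest on the correction, and the values the authors deposited, which hold the ChIP channel without input, called 264 higher and 230 lower.

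Over ORF features the Med15-myc ratios were highest at *prt2* (2.28 ± 0.29), SPAP15E9.02c (1.74 ± 0.25), the F-box gene *pof9* (1.63 ± 0.26), *mug114* (1.62 ± 0.26) and the TFIID gene *taf4* (1.59 ± 0.26). The lowest were the mitochondrial gene *cox2* (−5.58 ± 2.06), 3 features that the file names after a sequence entry (−3.74, −2.92 and −2.63) and *urf* (−2.91 ± 0.66). None passes: limma called 0 of 4857 ORF features as scanned, with 22 higher and 57 lower at unadjusted p < 0.05. Normexp called 7 higher and 15 lower, and all 7 were also called by loess (142 higher, 316 lower). The 7 were *prt2* (2.79 ± 0.20, adjusted p = 0.00029), *taf4* (1.98 ± 0.25, 0.0122), *mug114* (1.88, 0.037), SPAP15E9.02c (1.87, 0.0045), *pof9* (1.83), SPAC56F8.13 (1.54) and a feature whose name the file holds in a calendar form (1.71). The lowest under normexp were the mitochondrial *cob* (−3.12), *urf* (−2.58) and 3 features named after the same sequence entry, 2 of them the same as before. Leaving out replicates 1, 2 and 3 in turn gave 8, 65 and 1 higher and 14, 162 and 6 lower features with normexp, and 12, 65 and 246 higher and 66, 215 and 342 lower with loess, and the ChIP channel alone called 731 higher and 871 lower.

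Of the lists fixed before the data were examined, 3 of 27 lay above the rest of the IGR features as scanned (camera with the preset correlation). The histone genes had positive ratios at 9 of 10 features (adjusted p = 3.74e-06), with *hta1* at 1.94 ± 0.52, the H2B gene *htb1* at 1.81 ± 0.55, *hhf1* at 1.61 ± 0.75 (uncertain, since H4 copies share sequence) and *hta2* at 1.07 ± 0.48. Phosphate genes were positive at 5 of 6 (adjusted p = 0.00151), with the transcription factor gene *pho7* at 1.39 ± 0.53, the acid phosphatase gene *pho1* at 1.31, the glycerophosphodiester transporter gene *tgp1* at 1.24 and the phosphate transporter gene *pho84* at 1.23. Glycolysis genes were positive at 10 of 13 (adjusted p = 0.00684), with *pdc101* at 1.98 ± 0.51, *pfk1* at 1.53, *tpi1* at 1.20 and *gpm1* at 0.88. On the ORF arrays, ribosomal protein genes lay above the rest (84 of 113 positive, adjusted p = 1.96e-05 of 28 lists), with *rpl1001* at 0.77 ± 0.29, *rps1801* at 0.59, *rps102* at 0.52 and *rpl35A02* at −0.58, all uncertain as members of copied gene pairs. No member passed by limma, over all features or adjusted over the list alone. With an estimated correlation the adjusted p was 0.94 for the 3 IGR lists and 0.846 for the ribosomal proteins, so each call was made with the preset only. Camera with an estimated correlation takes p from the few residual degrees of freedom of 3 arrays, so a list can hardly pass it. The loss therefore does not show that correlation within a list made the call. The fry test, which asks whether a list differs from no change and not from the other features, gave 0.999 and 0.648.

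After normexp the same 3 IGR lists were called (histones adjusted p = 1.17e-07, glycolysis 7.96e-07, phosphate 0.000604; 0.928 for each with an estimated correlation). Of the histone genes 4 were enriched and 1 depleted (7 and 1 adjusted over the list alone), with *hta1* at 2.65, *htb1* at 2.29, *hhf1* at 1.84 (uncertain) and the centromeric H3 gene *cnp1* at −1.42. In glycolysis 4 were enriched (9 over the list alone): *pdc101* 2.45, the alcohol dehydrogenase gene *adh1* 1.74, *pfk1* 1.68 and the phosphoglycerate kinase gene *pgk1* 1.60. In the phosphate list 4 were enriched (4 and 1 depleted over the list alone): *pho1* 2.10, *pho84* 1.38, *tgp1* 1.30 and *pho7* 1.19. The histone chaperone list was not called (adjusted p = 0.525), yet 3 of its 17 genes were depleted (1 enriched and 3 depleted over the list alone), *nap2* at −1.40, *asf1* at −1.30 and *pcf2* at −1.26, beside *mis16* at 1.16, which did not pass. Calls of depletion over the IGR features numbered 0 without replicate 3 and 6 without replicate 1, so these calls change with the replicates used. Among 115 ribosomal protein genes (adjusted p = 0.55), 2 were enriched and 1 depleted (2 and 3 over the list alone): *rps1602* 1.68, *rps2202* 1.20 and *rpl3202* −1.22, all uncertain. On the ORF arrays 93 of 113 ribosomal protein genes were positive (adjusted p = 5.24e-08; 0.933 with an estimated correlation) with 0 called, and 20 enriched and 1 depleted under loess. These settings of the list tests were added after the data were seen.

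**Figure D2:**
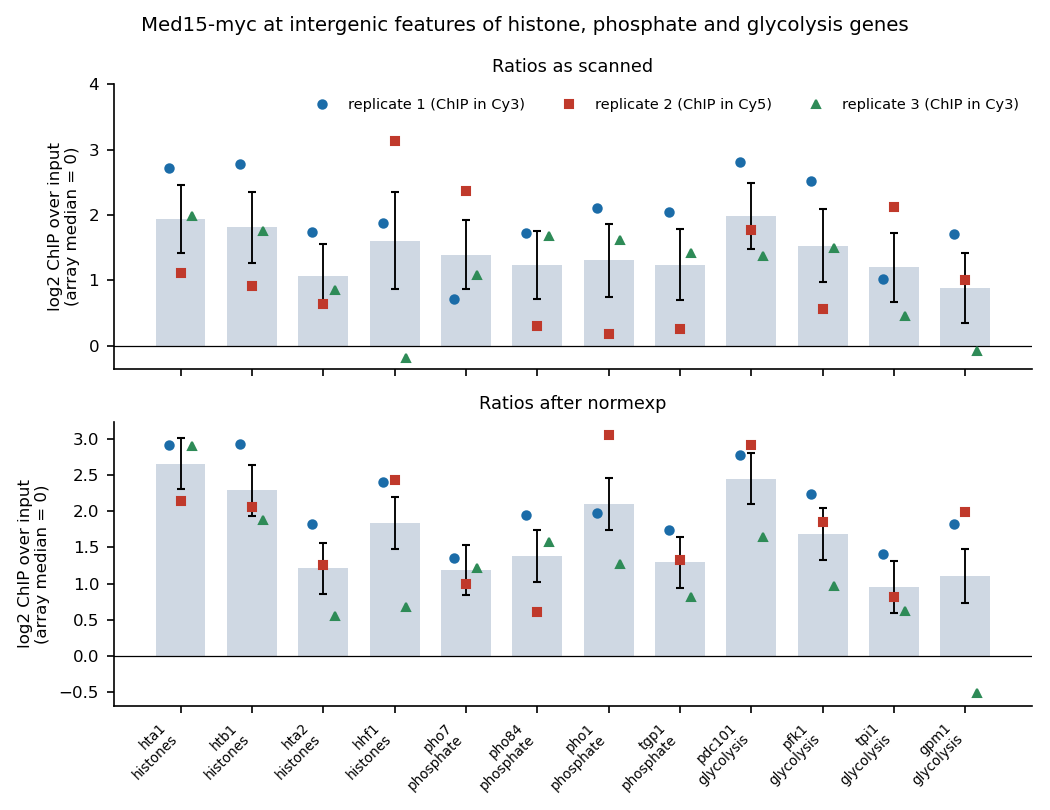
Log2 ratio of Med15-myc ChIP over input at 12 IGR features of histone, phosphate and glycolysis genes, as scanned and after normexp. Bars are means, error bars standard errors and points the 3 replicates.

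In Δmed15, H3 ChIP signal over IGR features was higher than in wildtype at SPAC1952.04c (7.47 ± 0.78, adjusted p = 0.0131, measured in 1 of the wildtype samples) and SPBPB2B2.19c (5.86 ± 0.78, 0.0205). It was lower at an alanine tRNA feature with the AGC anticodon (−5.72 ± 0.72, 0.0205), the mitochondrial import gene *tom20* (−5.46 ± 0.75, 0.0297), SPAC9G1.07 (−5.34 ± 0.65), SPAC1565.03 (−5.32 ± 0.61), SPAP11E10.01 (−5.14 ± 0.74), the thiamine gene *thi4* (−5.04 ± 0.75, 0.0466) and *rps2201* (−4.32 ± 0.62, uncertain as a copied gene). These are all 9 of 4866 features that limma called, 2 higher and 7 lower, against 384 and 538 at unadjusted p < 0.05. Each of the 9 was near background in 1 strain, so the sizes are not exact. As fitted values they can exceed the difference of the means: SPAC1565.03 read −4.26 in Δmed15 and −0.34 in wildtype. The next largest values, which do not pass, were *thc1* (4.22), *atp16* (4.20), SPCC63.06 (4.14) and *ngg1*, a gene of the SAGA complex (−6.81, near background, adjusted p = 0.0664). The signal is that of the ChIP channel alone and wildtype has no input, so a change in H3 occupancy cannot be separated from a difference in spot brightness between array sets. The count was 578 without Δhrp1 replicate 1 and 13 or fewer without any other sample, 90 (54 higher, 36 lower) with no dye covariate and 377 (158, 219) with arrays scaled to the same spread.

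In Δhrp1, H3 ChIP signal over IGR features rose at SPBPB2B2.19c (7.80 ± 0.68, adjusted p = 0.00232), the ATP citrate lyase gene *acl1* (5.68 ± 0.87, 0.0171), SPAC1952.04c (5.48 ± 0.72), a long tile at SPBC24C6.09c (4.65 ± 1.00), the mitochondrial import gene *tom7* (4.50), *rpl35A02* (4.42, uncertain), the kinesin gene *klp2* (4.16), *thc1* (4.08), *paa1* (4.0) and the RNA polymerase III gene *rpc1* (3.99 ± 0.69). It fell at *raf2*, which encodes a subunit of the H3K9 methyltransferase complex (−6.17 ± 0.70, 0.0121), *hmo1* (−5.07 ± 0.89), an intergenic feature without a gene name (−5.03), *tom20* (−4.97), *mrp10* (−4.96), *dsc4* (−4.95), the fumarase gene *fum1* (−4.82 ± 1.12, measured in 1 of the Δhrp1 samples), *sur2* (−4.81) and *rpl21* (−4.79, uncertain). In all, limma called 597 of 4866 features, 193 higher and 404 lower. Of these, 45 were near background in 1 strain, so their sizes are not exact, among them SPBPB2B2.19c, *acl1*, SPAC1952.04c, *raf2*, *hmo1*, the feature without a gene name, *tom20*, *mrp10* and *fum1*. The count was 2 without either wildtype sample and 907 without Δhrp1 replicate 1. Arrays scaled to the same spread gave 921 (354, 567).

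Between the deletions, the IGR features with the largest H3 ChIP differences were, higher in Δhrp1, the alanine tRNA feature (4.58 ± 0.61), SPAC977.15 (3.75), *mrpl19* (3.57), *ppa* (3.43) and *oar2* (3.41), and lower in Δhrp1 *sly1*, a gene of vesicle transport (−5.50 ± 0.85), the peroxisomal import gene *pex5* (−4.41), the nucleoporin gene *nup186* (−4.10), *wbp4* (−4.00) and an intergenic feature without a gene name (−3.71). None passes: limma called 0 features (adjusted p of 0.0801 or more for these), with 431 higher and 568 lower at unadjusted p < 0.05. Ratios of ChIP over input, which these 5 samples allow, called 0 as scanned, 3 with normexp and 6 with loess, and without Δhrp1 replicate 1 the ChIP channel called 806. Arrays scaled to the same spread gave 332 (160, 172). The alanine tRNA feature, SPAC977.15, *mrpl19*, *ppa*, *sly1* and *pex5* were near background in 1 strain, so their sizes are not exact.

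Over ORF features, H3 ChIP signal in Δmed15 rose at *arg5*, which encodes the small subunit of carbamoyl-phosphate synthase (7.70 ± 0.51, adjusted p = 0.00125), the thiamine gene *thi2* (4.51 ± 0.51), the ammonium transporter gene *amt1* (4.34 ± 0.50), *pob1* (3.79), SPAC977.17 (3.78), the DNA helicase gene *fml1* (3.77), the Golgi gene *cog3* (3.73), SPBPB10D8.01 (3.50), *mrz1* (3.49) and *gmh3* (3.48). It fell at SPAC57A7.05 (−9.10 ± 0.76, 0.00568), SPBC16A3.02c (−7.16 ± 0.67), *mde7* (−6.91), *ntu1* (−6.46), the mitochondrial genes *tim54* (−6.16 ± 0.50) and *msp1* (−5.95), *thrc* (−5.80), *bag101* (−5.72), the topoisomerase gene *top3* (−5.61) and *naa40*, an N-acetyltransferase gene (−5.47). Of the last 10, SPAC57A7.05, SPBC16A3.02c, *mde7*, *tim54*, *msp1* and *thrc* were measured in 1 of the Δmed15 samples. In all, limma called 264 of 4754 features, 146 higher and 118 lower. Of these, 26 were near background in 1 strain, so their sizes are not exact. They include *arg5*, *thi2*, *amt1* and the named falls other than *bag101* and *top3*. The count was 1 without either wildtype sample, 2 and 18 without Δmed15 replicates 1 and 2, 838, 173 and 6 without Δhrp1 replicates 1, 2 and 3, and 2 on the samples with ChIP DNA in Cy3. It was 663 (388, 275) with no dye covariate and 551 (265, 286) with arrays scaled to the same spread.

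In Δhrp1, H3 ChIP signal over ORF features rose at *arg5* (7.56 ± 0.44, adjusted p = 0.000246), *amt1* (5.59 ± 0.43, 0.00151), *thi2* (5.27), *mrz1* (4.05), the cysteine desulfurase gene *nfs1* (3.96), SPBPB10D8.01 (3.90), SPAC977.17 (3.80), *pob1* (3.69), the karyopherin gene *kap104* (3.66) and *tos4* (3.66). Below *hrp1* itself it fell most at the cytochrome b5 gene *cyb502* (−6.63 ± 0.79), SPCPB1C11.02 (−6.21), *kex1* (−6.08), *naa40* (−5.73), *mug116* (−5.72), the Arp2/3 gene *arc1* (−5.61), *tim54* (−5.50 ± 0.41), the DASH complex gene *dad5* (−5.27) and *sos7* (−5.18). In all, limma called 1306 of 4754 features, 645 higher and 661 lower, with 48 and 3 without wildtype replicates 1 and 2. Of these, 41 were near background in 1 strain, so their sizes are not exact, among them *arg5*, *amt1*, *thi2* and each of the falls just named.

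Between the deletions, H3 ChIP signal over ORF features was higher in Δhrp1 at SPBC16A3.02c (6.30 ± 0.55, adjusted p = 0.00639), SPAC57A7.05 (4.83), *med15*, the TFIIIC gene *sfc6* (3.97), SPAC11D3.01c (3.82), the DNA polymerase delta gene *cdm1* (3.75), the endonuclease gene *eme1* (3.37), SPAC1687.23c (3.14), SPAC4H3.09 (2.68) and SPAC683.03 (2.46). It was lower in Δhrp1 at *hrp1* (like *med15*, near background where it is deleted), SPCC126.11c (−6.45), *bxi1* (−6.30), the mitochondrial ribosome gene *mrpl17* (−6.13 ± 0.39, 0.00173), SPBC21H7.08 (−5.30), *psi1* (−4.49), *vht1* (−3.21), *lsm4* (−2.98), *utp23* (−2.49) and *rpl1202* (−2.37, uncertain). In all, limma called 25 features, 13 higher and 12 lower, and 8 or fewer without any 1 sample other than Δhrp1 replicate 1, whose removal gave 890. The count was 331 (148, 183) with no dye covariate and 575 (254, 321) with arrays scaled to the same spread. Of the 25, 12 were near background in 1 strain, so their sizes are not exact: SPBC16A3.02c, SPAC57A7.05, *med15*, *eme1*, SPAC683.03 and the named falls other than *vht1*, *utp23* and *rpl1202*. Divided by input, none was called as scanned, 0 with normexp and 3 with loess, and in 1 or more of these settings the values at SPAC57A7.05, SPBC16A3.02c, *med15*, *sfc6*, *cdm1*, *bxi1*, *mrpl17*, SPBC21H7.08 and *hrp1* took the other sign.

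Among gene lists on the IGR arrays, glycolysis was the only 1 of 26 called in Δhrp1 against wildtype: all 12 features were lower (camera adjusted p = 0.0128), and 4 fell (6 over the list alone), the pyruvate kinase gene *pyk1* (−3.89), the aldolase gene *fba1* (−3.97), the hexokinase gene *hxk2* (−2.84) and *gpm1* (−3.50). With an estimated correlation its adjusted p was 0.881, and fry gave 0.0607. Another 10 lists were not called (adjusted p of 0.717 or more) and held 3 or more called members, given here with standard errors of 0.52 to 1.12 and with counts over the list alone in parentheses. Over all IGR features limma called 597 of 4866, so called members alone are no sign of a shift of a list. Of 96 ribosomal protein genes 2 rose and 14 fell (2 and 14), with *rps1602* at −3.72, *rps2201* at −3.29, *rps1601* at −3.07 and *rpl35A02* at 4.42, all uncertain. Of 36 respiration genes 5 rose and 2 fell (5 and 2), with *atp16* at 3.62, *qcr9* at 2.26, *atp2* at 1.98 and *atp14* at −3.19. Of 24 heterochromatin genes 2 rose and 2 fell (2 and 3), with *clr6* at 2.41, *raf2* at −6.17 (near background) and the H3K9 methyltransferase gene *clr4* at −2.28. Of 15 Mediator genes 2 rose and 1 fell (2 and 1), *med6* at 3.72, *srb11* at 2.47 and *med7* at −4.45 (near background), with *med13* at −2.08 not passing. Of 27 kinetochore genes 3 rose and 2 fell (3 and 2), with *fta4* at 3.23 (near background), *mis13* at 3.17, *hos2* at 2.45 and *sim4* at −3.13. Of 18 cell wall genes 4 fell (4), with *psu1* at −3.18, *bgl2* at −2.48 and *meu10* at −1.90, and *ecm33* at −3.06 lies outside these counts because it was not measured in every sample. Of 39 meiosis genes 1 rose and 3 fell (1 and 3), *spo5* at 1.92, *mes1* at −2.96, *meu22* at −2.38 and *mei3* at −2.33. Of 24 mating genes 1 rose and 2 fell (2 and 2), *fus1* at 2.21, *ste6* at −3.57 and *mam1* at −2.66, with *mfm2* at 3.81 (near background) not passing. Of 30 basal transcription genes 1 rose and 2 fell (1 and 0), *taf6* at 3.14, *rpb2* at −2.68 and *tfa2* at −2.30, with *tfg1* at −1.54 not passing. Of 17 strain marker genes 2 rose and 2 fell (3 and 3), *ura5* at 3.33, *his7* at 3.09, *leu1* at −3.22 and *mam1* at −2.66. On the ChIP signal no IGR list was called in Δmed15 or between the deletions.

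On the ORF arrays the H3 ChIP signal of ribosomal protein genes, taken without input, lay lower in both deletions. The median change was −0.87 in Δhrp1 and −0.53 in Δmed15, and the loess ratios over input given below ran the other way between the deletions. In Δhrp1, 78 of 100 were negative (camera adjusted p = 0.000284; 0.992 with an estimated correlation; fry 0.0576), with 3 up and 24 down (3 and 24 over the list alone), *rpl6* at −4.38, *rps7* at −2.84, *rpl2001* at −2.56 and *rpl302* at 3.13. In Δmed15, 66 were negative (camera adjusted p = 0.0084, 0.973 with an estimated correlation, fry 0.271), with 1 up and 9 down (3 and 19 over the list alone), *rps3001* at −3.67, *rpl31* at −3.58 (near background), *rpl6* at −3.44 and *rpl2102* at −2.50, all uncertain where copies exist. Meiosis and respiration were not called in Δmed15 (adjusted p = 0.965 each). Of 40 meiosis genes 3 rose and 1 fell (4 and 3 over the list alone), *mug28* at 2.69, *meu7* at 2.49, *meu14* at 2.21 and *mes1* at −2.62. Of 36 respiration genes 2 rose and 1 fell (3 and 2), *cox4* at 2.70, *qcr6* at 2.48 and *atp16* at −2.37, with *atp2* at 1.80 not passing. Between the deletions, 11 of 12 Tf2 transposon features were higher in Δhrp1 (adjusted p = 0.0212; 0.963 with an estimated correlation; fry 0.0884), with 0 called over all features and 3 over the list alone, and with *Tf2-3* at 1.68, *Tf2-11* at 1.43, *Tf2-8* at 1.28 and *Tf2-7* at 0.98, all uncertain as copies. On ChIP over input with loess, a setting of the list tests added after the data were seen, camera called glycolysis (9 of 13 positive) and ribosomal proteins (83 of 115) higher in Δhrp1 than in Δmed15 over IGR features (adjusted p = 0.00499 each; 0.896 with an estimated correlation; fry 0.66). Over ORF features it called ribosomal proteins (78 of 113, adjusted p = 0.0406; 0.827 with an estimated correlation; fry 0.701), with 0 members called in these lists, and normexp ratios called no list.

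The remaining ORF lists with 3 or more called members in Δhrp1 were not called by camera (adjusted p of 0.95 or more). Over all ORF features limma called 1306 of 4754 in Δhrp1, so called members alone are no sign of a shift of a list. Members up and down are given as 2 numbers, with those over the list alone in parentheses, and standard errors ran from 0.35 to 0.85. Histones gave 0 and 4 (1 and 4), with *htb1* at −3.41, *hhf2* at −2.90 and *hht2* at −1.29 (both uncertain) and *hta1* at −1.62. Glycolysis gave 1 and 4 (2 and 4), with *adh1* at −5.09 (near background), *gpm1* at −3.32, *gpd3* at −2.67 and *pdc201* at 1.32. Transposons gave 3 and 1 (3 and 1), *Tf2-11* at 1.86, *Tf2-2* at 1.55, *Tf2-8* at 1.54 and *Tf2-1* at −1.56, all uncertain. The heterochromatin list gave 3 and 6 (3 and 6), with the telomere gene *taz1* at 2.70, the deacetylase gene *sir2* at 2.35, *epe1* at −2.71 and *ers1* at −3.37. Mediator gave 4 and 1 (4 and 1), with *med13* at 2.17, *med11* at 1.78, *med6* at 1.56 and *srb10* at −3.05. Remodellers gave 2 and 2 (2 and 2), *snf21* at 1.96, *fft1* at 1.83, *fft2* at −2.51 and *hrp1*. Histone chaperones gave 3 and 4 (4 and 4), with *nap2* at 2.50, *mis16* at 1.86, *mis18* at −2.43 and the FACT gene *pob3* at −2.75. Kinetochore genes gave 5 and 2 (5 and 3), with *ndc80* at 2.46, *fta3* at 1.77, *mis16* and *mis18*. Basal transcription gave 3 and 1 (0 and 0), with *rpb7* at 1.86, *tfb2* at 1.54 and *taf6* at −2.06, and *taf7* at −2.99 lies outside these counts because it was not measured in every sample. Ribosome biogenesis gave 5 and 5 (5 and 5), with *nop14* at 3.09, *cbf5* at 3.07, *utp13* at 2.69 and *ebp2* at −2.28. Respiration gave 5 and 3 (5 and 3), with *atp2* and *cox4* at 2.51, *coq7* at −2.16 and *cox5* at −3.52. The proteasome gave 4 and 2 (3 and 2), with *pup2* at 1.98, *rpn8* at 1.44, *rpt1* at −1.98 and *rpt5* at −2.34. Meiosis gave 5 and 7 (5 and 8), with *meu14* at 2.78, *mug28* at 2.48, *rec10* at 1.68 and *rec12* at −4.18, and mating 4 and 1 (4 and 1), with *fus1* at 2.94, *spk1* at 2.12, *sxa2* at 1.94 and *map4* at −2.36. Cell separation gave 2 and 3 (2 and 3), with *spo12* at 1.40, *adg2* at −2.0, *fin1* at −2.56 and the Polo kinase gene *plo1* at −3.41. Flocculins gave 5 and 2 (5 and 2), with *ldb1* at 2.70, *gsf2* at 1.92, *pfl9* at 1.75 and *map4*, and the cell wall list 2 and 2 (1 and 2), *gas4* at 2.70, *pwp1* at 1.58, *gas5* at −2.32 and *ecm33* at −4.28. Among nutrient lists, hexose gave 3 and 3 (5 and 4), with *icl1* at 2.82, *ght3* at 1.84, *inv1* at 1.64 and *agl1* at −1.53, and nitrogen 3 and 2 (3 and 2), with *amt1*, *fnx2* at 2.99, *inv1* and *put4* at −2.21. Iron gave 2 and 2 (2 and 3), *pcl1* at 2.85, *str1* at 1.68, *fio1* at −1.63 and *sib2* at −2.14, and copper and zinc 2 and 1 (2 and 2), *zrt1* at 2.38, *ctr6* at 1.39 and *zip1* at −2.17, with *ctr5* at −1.08 not passing. The stress response list gave 2 and 4 (2 and 4), with *tms1* at 1.93, *pyp2* at 1.87, *cip2* at −1.64 and *pcr1* at −2.41.

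The deletions shared H3 ChIP calls. On the ORF arrays 137 features were higher and 73 lower in both against wildtype, *arg5*, *amt1*, *thi2*, *pob1*, *tim54* and *naa40* among them, where 19.8 and 16.4 are expected by independence, and 1 moved in opposite directions. On the IGR arrays 2 were higher, SPAC1952.04c and SPBPB2B2.19c, and 5 lower, *tom20*, *thi4*, *rps2201*, SPAC1565.03 and SPAC9G1.07 (0.0793 and 0.581 expected). The changes correlated with r of 0.707 over IGR and 0.729 over ORF features, where groups simulated without change gave 0.605 and 0.606, and their covariance was 1.36 and 1.19 against 0.292 and 0.161. The simulated groups shared 0 IGR calls on average and at most 2 ORF calls in 100 draws. Groups without change give almost no calls, so this does not show how many calls unrelated changes would share against the same wildtype arrays. Both comparisons use the same 2 wildtype arrays. With 1 wildtype array for each comparison, set both ways round after the data were seen, r was 0.672 and 0.567 over IGR features (0.0915 and 0.0917 in simulated groups) and 0.692 and 0.643 over ORF features (0.0924 and 0.0886), with 0 IGR calls and 1 ORF call shared. A difference that both wildtype arrays have in common from the arrays of the deletions is not removed by this split.

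RNA of Δmed15 differed from wildtype at 1647 of 8572 probe sets (limma), 897 higher and 750 lower, of which 359 rose and 242 fell by at least 2-fold. The files do not name the genes of the probe sets other than controls, so the largest changes are given by probe set: 1770831_at (adjusted p = 0.0343) and 1772862_s_at rose, and 1778122_at (0.0124) and 1770512_at (0.0188) fell. Each read near background in 1 strain, and 1770512_at in both, so no size is given. As near background was taken, after the data were seen, a mean log2 signal of 1.91 or lower, the 95th percentile of 47 reporter control probe sets. Of all 8572 tested probe sets, which may include ones for *S. cerevisiae*, 3478 lay near background in both strains. Of the 1647, 133 lay near background in both strains and 36 in 1, and the other 1478 split into 828 higher and 650 lower. Centring on the median gave 491 higher and 1079 lower, since the median probe set lay 0.22 above wildtype, so the balance of rises and falls rests on the scaling. Leaving out any 1 sample gave 0, or 80 without Δmed15 replicate 1, and the fit of these 4 samples alone called 0, while under a stricter filter on dim probe sets (added after the data were seen for these fits) the counts without a sample were 2069 to 2535.

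RNA of Δhrp1 differed from wildtype at 1 probe set, 1773549_at (4.15 ± 0.12, adjusted p = 0.0327), which was also high in Δmed15 (3.59). With 567 probe sets higher and 343 lower at unadjusted p < 0.05, the largest that did not pass were a rise of 1775758_at (adjusted p = 0.345) and falls of 1776649_at (0.118) and 1776161_at, all near background in Δhrp1 or in both strains, so no size is given. The stricter filter called 229 (135 higher, 94 lower) and a mean-variance trend 213. Leaving out any 1 sample gave 0, and under the stricter filter 95 and 165 without wildtype replicates 1 and 2, 44 and 26 without Δhrp1 replicates 1 and 2, and 298 without either Δmed15 sample. Between probe sets with mean log2 signal above 5, the standard deviation of the difference between arrays was 0.606 to 0.698 for wildtype against Δmed15, 0.254 to 0.306 for wildtype against Δhrp1 and 0.155 to 0.186 between replicates.

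Δhrp1 differed from Δmed15 at 1316 probe sets, 634 higher and 682 lower in Δhrp1, with 1778122_at (adjusted p = 0.0169) and 1773486_at highest and 1776649_at (0.0169) and 1775843_at (−5.21) lowest. The first 3 read near background in 1 strain or, for 1773486_at, in both, so no size is given. Of the 1316, 122 lay near background in both strains and 28 in 1. Probe set 1778122_at read 6.83 in wildtype, −2.39 in Δmed15 and 6.71 in Δhrp1, and 1776649_at read 7.66, 7.31 and 0.10, and each was the only probe set lost by more than 5 log2 units in just that strain, down to background. Centring gave 772 higher and 373 lower in Δhrp1, with a median shift of −0.16. Leaving out any 1 sample gave 0, or 1 without Δmed15 replicate 1, and 1881 to 2450 under the stricter filter.

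**Figure D3:**
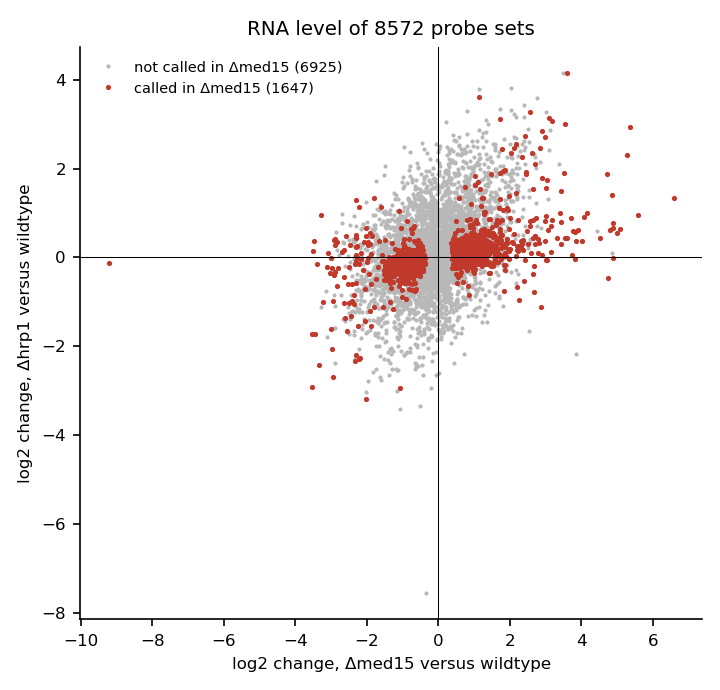
Log2 RNA change of each probe set in Δmed15 (horizontal) and Δhrp1 (vertical) against wildtype. The 1647 probe sets called in Δmed15 are red and the other 6925 grey.

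The probe sets called in both deletions numbered 1, 1773549_at, with 0.105 expected. Without a p, 941 probe sets changed by at least 1.5-fold the same way in both (569 higher and 372 lower, with 235 and 139 expected) and 230 in opposite directions, and under the stricter filter, added after the data were seen, 141 were called in both (92 higher and 49 lower, with 42.5 and 27.2 expected). The changes correlated with r = 0.406, below the 0.501 of simulated unchanged groups that share the wildtype arrays, while their covariance was 0.246 against 0.149 simulated. Under the stricter filter r was 0.464 against 0.501 and the covariance 0.0628 against 0.00524. With 1 wildtype array for each comparison, set both ways round after the data were seen, r was 0.0431 and 0.0812 (−0.00366 and 0.000776 in simulated groups) with 0 shared calls.

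The control probe sets of the array carry gene names, and 29 of them target *S. pombe* RNA (adjusted over these alone). The 5′ probe set of GPD3, a glyceraldehyde-3-phosphate dehydrogenase gene, rose in Δmed15 (2.61 ± 0.08, adjusted p = 0.000165, from a signal of 159 to 974) and in Δhrp1 (1.23 ± 0.08, 0.00343), and its middle probe set rose in Δmed15 (0.93 ± 0.13, 0.0092) and lay at 0.69 in Δhrp1 (0.0542). The middle and 3′ GPD3 probe sets marked as shared with other transcripts lay at −0.10 and −0.19 in Δmed15 and near 0 in Δhrp1. All 3 probe sets of SRB4, a Mediator subunit gene, fell in Δmed15 by 0.67 to 0.93, and all 3 of URA4 by 0.47 to 0.57, where the 3 actin probe sets lay between −0.06 and −0.14 and did not pass. Ribosomal RNA probe sets fell in Δmed15 by unlike sizes, 18S by 3.13 at its middle to 4.61 ± 0.40 at its 3′ end (adjusted p = 0.0092 and 0.00446). The 28S probe sets fell by 1.03 to 1.98 and 5.8S by 0.48 ± 0.10 (0.0181). At the 18S 3′ probe set the 2 wildtype arrays themselves read 514 and 257. In Δhrp1 the 18S 3′ probe set lay at −2.16 (0.0542). These controls were looked at after the probe sets were found to lack names.

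**Figure D4:**
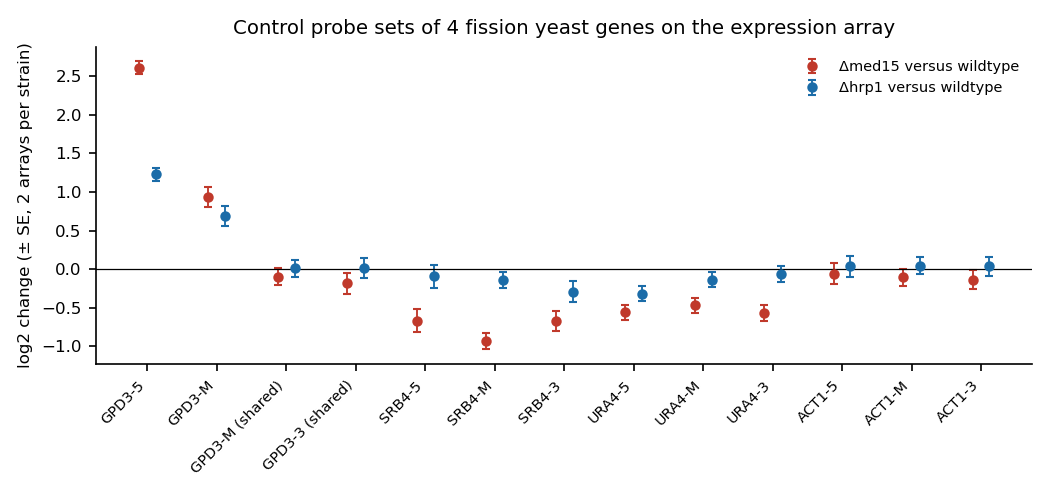
Log2 RNA change with standard error of control probe sets for GPD3, SRB4, URA4 and ACT1 in both deletions against wildtype. Probe sets marked as shared with other transcripts are labelled.

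Across features, H3 ChIP change and Med15-myc ratio were weakly related. In Δmed15, Spearman rho was 0.110 over 4866 IGR features and 0.108 over 4754 ORF features, and in Δhrp1 it was 0.123 over ORF and −0.058 over IGR features. The first 3 had permutation p = 1.0e-05, the smallest possible (adjusted 1.3e-05 over 4 tests), and the last 4.0e-05 (adjusted 4.0e-05). Pearson r was 0.0435 and 0.0444 in Δmed15 (p = 0.0023 and 0.00237, adjusted 0.00316), 0.0260 over ORF (p = 0.0720) and −0.114 over IGR features in Δhrp1 (p = 1.0e-05, adjusted 4.0e-05). With no dye covariate each rho kept its sign, but over ORF features in Δmed15 it was 0.034 (permutation p = 0.0185). Pearson r over ORF features was then −0.014 in Δmed15 (p = 0.351) and −0.0067 in Δhrp1 (p = 0.644). Features are not independent replicates. With normexp values of Med15-myc rho was −0.086 over IGR and −0.00086 over ORF features in Δmed15, and −0.188 over IGR (permutation p = 1.0e-05) and 0.015 over ORF features in Δhrp1. With loess values it was 0.141 over IGR and 0.111 over ORF features in Δmed15, 0.129 over ORF and 0.050 over IGR features in Δhrp1, a change of sign over IGR features in Δhrp1 only. With normexp the other 3 relations reversed or came near 0.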

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

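Of the tests in this part, the one for regions that give a high ratio with any antibody was written before its result was seen, and the tests of spot brightness, H3 occupancy, Cy5 background, a hybridisation without signal, mRNA integrity, shared probe sets and scaling were chosen after the results were seen.

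A signal appeared in spots that no comparison uses: the KanMX control spots of the ORF arrays had a centred log2 ratio of ChIP over input of 2.36 ± 0.63 (SD of 3 samples, 1.72 to 2.97) in Med15-myc, against −0.885 ± 0.27 in the 5 H3 samples of the deletion strains. A difference between the deletions was found by its own test at 1316 probe sets of RNA. The same holds for 25 ORF features of H3 ChIP.

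H3 ChIP signal differed from wildtype at many features in both deletions. If the brightness of the spots in each array set were the cause, input DNA of the deletion samples, which saw no antibody, should give the same sign in place of ChIP DNA. It did at 94.97% or more of the called features in each comparison, but both changes are taken from the same wildtype ChIP arrays at features chosen against them, so a high share decides nothing. An H3 occupancy that depends on Med15 or Hrp1 needs the ratio over input in wildtype, which has no input here, and at ORF features lower in Δhrp1 the ratio differed from Δmed15 by a median of −0.237. Brightness and occupancy cannot be told apart, and input DNA of wildtype on the same arrays would be needed.

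Med15-myc gave 0 calls as scanned and 61 IGR features with normexp. A background in the Cy5 channel that adds to the signal may be the cause. The mean rank correlation of the Cy5 replicate with the others went from −0.290 as scanned to 0.387 with loess. Loess removes any dye bias that depends on intensity, so this rise cannot single out an added background. With replicates 1 and 3 the Cy5 replicate had rho of 0.339 and 0.135 with normexp, and 0.322 and −0.041 with local background subtracted. A hybridisation without any signal of the sample in that replicate is argued against by its rho with loess of 0.487 with replicate 1 and 0.288 with replicate 3, but a partial loss stays open (0.135 with replicate 3 with normexp and −0.041 with local background subtracted). For regions that come down with any antibody, the test written beforehand took an H3 ratio below 0 at the 61 features as evidence against, and the highest sample median was −0.936. That test was wrong by design, since H3 reads low wherever nucleosomes are few, and with normexp the 165 long intergenic tiles had a median of 0.43 for Med15-myc and 0.50 for H3, though not in each H3 sample (−0.35 in Δhrp1 replicate 3), so this explanation and binding of tagged Med15 stay open without an untagged control.

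The 5′ probe set of GPD3 rose in both deletions while its shared 3′ probe set did not. Strain differences in mRNA integrity are argued against, as the median 5′ minus 3′ shift of the other 6 mRNAs was 0.0615 in Δmed15 against 2.80 for GPD3, while integrity of ribosomal RNA stays open (18S shifted by 1.30 in Δmed15 and 0.93 in Δhrp1, 28S by −0.94 and −0.38). Scaling is excluded, since the largest change of an actin probe set was −0.138. For signal of another transcript in the shared probe sets, the unmarked middle probe set rose by 1.03 more than the marked middle one in Δmed15 and by 0.683 more in Δhrp1. This restates the pattern to be explained, so it cannot test the explanation. Shared probe sets that add GPD3 to a constant second transcript should rise with GPD3. In Δmed15 the shared middle and 3′ probe sets instead went from 1047 to 980 and from 1336 to 1177, changes that did not pass. What the array measured stays open, and a probe unique to the 3′ end would test it.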

How the results depend on the processing

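The tests here that were chosen after the results were seen are local background subtraction, normexp with loess, floor values kept for H3, ChIP over input of H3 with normexp or loess, Med15-myc values with normexp or loess in the relations, the stricter filter for shared RNA calls, and separate wildtype arrays for shared calls. Of 145 alternatives to 26 results, 66 kept the direction and the side of the threshold or stayed within 1.5 times the count, and 79 did not, and of 66 fits without a sample 21 did. Unless the construction shows it, the cause was not tested.

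Med15-myc features called enriched, 0 in both as scanned, numbered 61 (IGR) and 7 (ORF) with normexp and 165 and 142 with loess. There were 79 and 38 with normexp and loess, 2 (ORF) with dim features left out and 1 (ORF) with local background subtracted. On the deposited ChIP channel, which has no input, 264 (IGR) and 731 (ORF) were called higher than the array median. Those calls cannot tell binding of Med15 from bright spots. Signal over background limits the ratios of dim spots: on the IGR arrays the median ChIP signal of replicate 2 in Cy5 was 7882 over a background of 4880, against 4219 over 87.8 for replicate 1 in Cy3. Without each replicate as scanned the counts stayed at 0 to 0.

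For H3, in the order IGR Δmed15, IGR Δhrp1, IGR between deletions, ORF Δmed15 and ORF between deletions, arrays scaled to the same spread gave 377 (158 up, 219 down), 921 (354, 567), 332 (160, 172), 551 (265, 286) and 575 (254, 321). With no dye covariate there were 90 (54, 36) in IGR Δmed15, 663 (388, 275) in ORF Δmed15, 331 (148, 183) in ORF between deletions, and 56 (48, 8) IGR and 481 (318, 163) ORF shared calls. Only samples with ChIP DNA in Cy3, which are fewer, gave 0 in IGR Δmed15, 2 (1, 1) in ORF Δmed15 and 1 (0, 1) in ORF between deletions. Features measured in all 7 samples gave 5 (1, 4) in IGR Δmed15 and 8 (5, 3) in ORF between deletions. Floor values kept gave 17 (2, 15) in IGR Δmed15, 340 (95, 245) in IGR Δhrp1 and 5 (1, 4) in IGR between deletions. The ranges without each sample were 0 to 578 in IGR Δmed15, 2 to 907 in IGR Δhrp1, 0 to 806 in IGR between deletions, 1 to 838 in ORF Δmed15, 3 to 1408 in ORF Δhrp1 and 1 to 890 in ORF between deletions. ORF Δhrp1 stayed within 1.5 times under every other alternative. A lone sample left in a strain is assumed to vary like the other groups.

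ChIP over input of the 5 deletion samples, fewer than in the fit of all 7, gave between deletions 0 ORF features as scanned, 3 IGR (2, 1) and 0 ORF with normexp, and 6 IGR (5, 1) and 3 ORF (3, 0) with loess. Named features that reversed were, as scanned on ORF, SPAC57A7.05 (−0.37) and *med15* (−0.050). With normexp they were *med15* on IGR (2.69) and on ORF *hrp1* (0.034), *sfc6* (−0.24), SPAC57A7.05 (−0.13), SPBC16A3.02c (−0.19), SPBC21H7.08 (0.13) and *bxi1* (0.011). With loess they were *med15* on IGR (2.42) and on ORF *cdm1* (−0.053), SPAC57A7.05 (−0.41), SPBC16A3.02c (−0.072), SPBC21H7.08 (0.072), *mrpl17* (0.12) and *bxi1* (0.20). At its ORF feature a deleted gene should leave no DNA in either channel, so its ratio there rests on what is left of both signals. This does not hold for the *med15* IGR feature. Its input in Δmed15 was 1656 over a local background of 3 and 5857 over 695.5. Both reversed IGR values passed by limma (adjusted p = 0.00254 with normexp and 2.71e-05 with loess).

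For RNA, in the order Δmed15, Δhrp1 and between deletions, a mean-variance trend gave 2787 (1510 up, 1277 down), 213 (144, 69) and 2644 (1242, 1402), an offset of 16 gave 2833 (1563, 1270), 206 (135, 71) and 2728 (1255, 1473), and the stricter filter 2590 (1348, 1242), 229 (135, 94) and 2481 (1175, 1306). No filter gave 1050 (590, 460), 0 and 664 (312, 352), and only the 4 samples of the strains compared, which are fewer, gave 0, 0 and 0. Quantile normalization, centring and the 1.5-fold threshold stayed within 1.5 times. Shared calls were 941 (569, 372) at 1.5-fold without a p and 141 (92, 49) with the stricter filter. With separate wildtype arrays for the deletions, both ways round, shared calls were 0 and 0 for RNA, 0 and 0 for H3 IGR and 1 and 1 for H3 ORF, with 1 wildtype sample left in each fit. The ranges without each sample were 0 to 80, 0 to 0 and 0 to 1.

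With replicate number as a block (replicate block), RNA gave 952 (556, 396), 0 and 0, and H3 with the dye covariate 187 (74, 113) in IGR Δmed15, 1078 (359, 719) in IGR Δhrp1, 121 (23, 98) in IGR between deletions and 131 (19, 112) in ORF between deletions. Nothing in the labels pairs samples by number: residuals of equal numbers correlated with r of −0.00861 to 0.0231 in RNA, 0.117 to 0.202 in H3 IGR and 0.0249 to 0.333 in H3 ORF.

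In the fits with the dye covariate for H3 and as scanned for Med15-myc, every list that camera called with the preset correlation was lost with an estimated correlation, and fry, which tests a list against no change and not against other features, called none of them as moved in 1 direction: 0 and 0 for Med15-myc IGR (3 lists), Med15-myc ORF, H3 IGR Δhrp1, H3 ORF Δmed15, H3 ORF Δhrp1 and H3 ORF between deletions. With no dye covariate fry called H3 IGR Δhrp1 glycolysis (adjusted p = 0.0470), ORF Δhrp1 ribosomal proteins (0.0111) and ORF between-deletion transposons (0.0252), and beyond the lists that camera called IGR Δhrp1 heat shock (0.0470), ORF Δhrp1 respiration (0.0111) and glycolysis (0.0329) and ORF between-deletion strain markers (0.0252). It did not call ORF Δmed15 ribosomal proteins (0.0698), and camera with an estimated correlation called none of these (0.393 or more). With an estimated correlation camera takes p from the few residual degrees of freedom of each fit, so a list can hardly pass. These losses therefore cannot tell whether correlation within the lists made the calls. In the relation of H3 change with Med15-myc ratio, normexp values gave rho of −0.086 (IGR Δmed15, reversed), −0.00086 (ORF Δmed15, reversed) and 0.015 (ORF Δhrp1, no longer past the threshold), and loess values 0.050 (IGR Δhrp1, reversed).

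Among named features under the other alternatives, 840 of the values for ORF Δhrp1 of H3 kept direction and side of the threshold and 3 no longer passed, and the numbers were 441 and 42 in IGR Δhrp1, 221 and 28 in ORF Δmed15, 82 and 15 in IGR Δmed15, 161 and 64 in ORF between deletions, 125 and 36 for RNA in Δmed15 and 114 and 48 between deletions. Of named Med15-myc features, 72 IGR and 49 ORF values newly passed. Not run, for want of gene names of the RNA probe sets, were the list tests on RNA, the relations of RNA with Med15-myc or H3, and fits within classes of expression.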

Other observations

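The groups in the next paragraph were put together after the results were seen, with 8 tests in their family, and the test for the side of the gene on which IGR features lie was written before its result was seen.

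In ChIP over input of H3 in the 5 deletion samples, the 18 tRNA genes had a median log2 ratio of −1.04 and none was positive (permutation p = 1.0e-05, the smallest possible; adjusted 1.6e-05), with sample medians of −0.34 to −1.31. The 165 long intergenic tiles had a median Med15-myc ratio of 0.42 as scanned, with 142 positive (permutation p = 1.0e-05, adjusted 1.6e-05), 0.43 with normexp and 0.25 with loess, and their H3 ratio was 0.50, but −0.35 in Δhrp1 replicate 3. The permutations treat features as independent, which they need not be, so these p-values do not measure the spread between samples. The mitochondrial genes *cox1*, *cob* and *cox2* had an H3 ratio of −3.95 (−3.10 to −4.70 by sample) and a Med15-myc ratio of −2.54 with normexp, without a test. At 3 features of the centromere central core the H3 ratio was −1.41 (0.66 in Δhrp1 replicate 3). At 2 features of the 5S rRNA promoter the Med15-myc ratio was 1.25 as scanned, 1.17 with normexp and 0.34 with loess. Over the 61 IGR features enriched for Med15-myc with normexp, the H3 ratio had sample medians of −0.936, −0.96, −1.03, −1.35 and −1.41, and over the 7 ORF features −0.98 to −2.35.

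A hypothesis was that IGR features lie upstream of the gene that names them, in which case neighbours transcribed away from each other should have more similar ratios than neighbours transcribed towards each other. Spearman rho was 0.111 over 1002 pairs transcribed apart, 0.058 over 431 pairs transcribed towards each other and 0.038 over 1735 pairs in tandem, a difference of 0.0534 as scanned, 0.150 with normexp and 0.230 with loess. The difference set beforehand was over 0.2, without naming a treatment, and it was met with loess only, so the features may lie upstream but the hypothesis stays open.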
